A study of Mus musculus with 6 samples.

How the data were processed

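Total RNA of 6 samples was amplified and biotin-labelled with Illumina's TotalPrep chemistry and hybridised to 1-colour Illumina mouse bead arrays, per the labels' protocols. Groups were taken from the sample labels: P0 (unpassaged, on gelatin), P6 on mesenchyme 1 and P6 on mesenchyme 2, with 2 arrays each. The series' design text calls the arrays of a group technical duplicates. The labels name no separate cultures, so p-values measure only the spread between these arrays.

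The values used are the deposited normalized intensities of the authors' value table, on a linear scale and all above 0. BeadStudio is named in the submitters' processing notes, with no version and no role. The background correction, the normalization method and the rule by which probes were kept are not given in the sources used here. Array medians were 128.3 and 129.8 for P0, 127.8 and 127.6 for mesenchyme 1, and 134.9 and 135.5 for mesenchyme 2, so the highest exceeded the lowest by 6.23%; values were not centred per probe. The table holds 11097 of the 25697 probes in the list of the deposited scanner table (43.2%), so a gene not named here may have been left out before deposit, and all folds are those of probes the authors kept. The scanner table holds a signal and a detection p-value per probe, per the file header, in 12 columns whose names match no sample label. None of them was used, since the rule followed here gives a column a sample only by its name. The analysis planned before the data were examined was to start from that table with a background from detection p-values, quantile normalization and a detection filter. Under this rule it could not be run. The deposited intensities, planned as an alternative, became the main values, with no further normalization and no filter. This choice was made after the files were seen. Without detection p-values, it is not known which intensities lie above background.

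Probes were named through the platform annotation, which gives 1 symbol for 10475 probes, several for 0 and none for 622. Entrez identifiers of 10471 probes matched a RefSeq gene table of mouse assembly GRCm38.p6, used for names only, and this changed 0 symbols. No genome build is named by the files, and no coordinates are given. For the 2007 genes with several probes, the probe with the highest mean log2 value over all arrays stood for the gene. Fold changes of that probe and the gene's next brightest correlated across genes at 0.62, 0.882 and 0.868 for mesenchyme 1 against P0, mesenchyme 2 against P0 and mesenchyme 2 against mesenchyme 1. A further probe was called in the opposite direction for 1 gene, Papola, in the last of these. Unnamed probes stayed in the tests, which gave 8396 features for 7774 named genes.

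Log2 intensities were fitted with limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit, eBayes) with 1 mean per group over all 6 arrays, which left 3 residual degrees of freedom and a prior of 3.81. P-values were two-sided and adjusted by Benjamini-Hochberg over all features within a contrast. A feature was called at an adjusted p under 0.05 and a fold change of at least 2. The contrasts were the 3 pairwise ones and the mean of both P6 groups against P0. In data simulated for the comparison of mesenchyme 1 with P0 over 8396 features, 96 of 100 features changed by 1.5 (log2) and 96 of 100 changed by 2 were recovered, with 1 false call. Unchanged groups sharing the P0 arrays were simulated 100 times from the spread between duplicates; these simulations cover array noise only.

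The text names, by a rule set before the data were examined, the 12 largest rises and 12 largest falls of each pairwise comparison among called genes whose arrays did not overlap, leaving out unnamed probes, clones and predicted gene models. It also names up to 2 rises and 2 falls per gene list described, or its 2 brightest members where none was called. All members of a count of 5 or fewer may be named, but need not be. A fixed set is named whatever its values (Sox17, Foxa2, Cxcr4, Gata4, Gata6, Epcam, Cdh1, Pou5f1, Nanog, Pdx1, Afp, Col1a1, Vim). Genes named outside this rule are said to be so. Gene lists, 36 in all, were written before the data were examined from general knowledge of endoderm, other lineages, signalling, metabolism and stress. The 30 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, then with the correlation estimated, and with fry. Of the 4 contrasts, the preset test called 6, 19, 19 and 14 lists (mesenchyme 1, mesenchyme 2, mesenchyme 2 against 1, mean), and with an estimated correlation 0, 0, 0 and 0 of them held. The estimated form of camera also works with the few residual degrees of freedom, so a lost call need not mean correlated members. The estimate lay below the preset 0.01 for parietal endoderm (-0.0326), visceral endoderm (-0.0518), S phase (-0.0615) and interferon-stimulated genes (-0.0269), among others. For these lists correlation cannot have cost the call. It lay above 0.01 for other lists, among them liver (0.126), epithelial junctions and keratins (0.127) and immediate early and stress (0.0841). The number of called members was the same adjusted over the list alone as over all features, for all 30 lists in each contrast.

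Alternatives planned beforehand were median scaling, the mean of all probes of a gene, the adjusted p alone, a test against a 2-fold change (treat), fits on the compared groups only, trend and robust priors, the replicate number as a block, leaving out each array, and averaged duplicates. Added after seeing the data were 16 or 50 added to every intensity, a mean intensity of at least 50 and quantile normalization of the deposited values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.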

Results

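Messenger RNA was measured on 1-colour Illumina bead arrays in endoderm, the germ layer of the gut lining and its glands, made from mouse embryonic stem cells of the R1 strain. The cells carried a GFP construct for Sox17, a transcription factor of the endoderm, and were treated with Activin A and Wnt3A for 6 days. Cells with the reporter signal were collected by fluorescence-activated sorting. RNA came from 3 groups: unpassaged cells on gelatin (P0), cells after 6 passages on a mouse mesenchyme called mesenchyme 1, and cells after 6 passages on mesenchyme 2. The labels do not say which tissues the mesenchymes came from. Each group had 2 arrays, which the series describes as technical duplicates, so n = 2 arrays and 1 culture per group. The deposited table gave a normalized intensity for 11097 probes per array, with array medians between 127.6 and 135.5. Levels below are geometric means over the 2 arrays, and differences are log2 values ± the standard error of the limma fit.

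Across probes, which are not independent replicates, log2 values correlated at 0.9934 to 0.9939 within groups. Between groups the highest correlations were 0.9596 for P0 with mesenchyme 1, 0.9059 for P0 with mesenchyme 2 and 0.8755 for the cultures on the different mesenchymes. P-values rest on the spread between technical duplicates and say nothing of the spread between cultures. Precision is limited by the number of arrays. No detection call was used, so a low intensity may lie at background. The median spread between duplicates was 0.206 (log2 SD) in the lowest quartile of intensity and 0.0768 in the highest.

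The transcript of Sox17, the gene behind the sort, was checked first in every group. It stood at 96.5 on the arrays labelled P0, 81.8 on those labelled mesenchyme 1 and 701 on those labelled mesenchyme 2. The arrays labelled mesenchyme 2 were above those labelled P0 by 2.86 ± 0.0994 (7.26-fold, adjusted p = 3.12e-06) and above those labelled mesenchyme 1 by 3.10 ± 0.0994 (8.56-fold, adjusted p = 1.77e-06). The difference between mesenchyme 1 and P0 was -0.24 ± 0.0994 (adjusted p = 0.0868) and did not pass. All groups were sorted on the reporter of this gene, so its level is a property of the sort as well as of the cells, and groups are named as labelled throughout. On P0 and mesenchyme 1 the Sox17 level lay below the array medians. The pluripotency gene Pou5f1 stood at 2833, 2280 and 1018 in P0, mesenchyme 1 and mesenchyme 2, and Nanog at 2310, 2001 and 1632. Levels of different probes need not compare as amounts. The word endoderm follows the labels, and the identity of the cells was not tested. Of the other genes fixed for reporting, Cdh1, an epithelial cadherin, stood at 937, 1133 and 1008 in P0, mesenchyme 1 and mesenchyme 2, and passed in no comparison. Foxa2, Cxcr4, Epcam, Pdx1 and Col1a1 have no named probe in the analysed table.

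**Figure D1:**
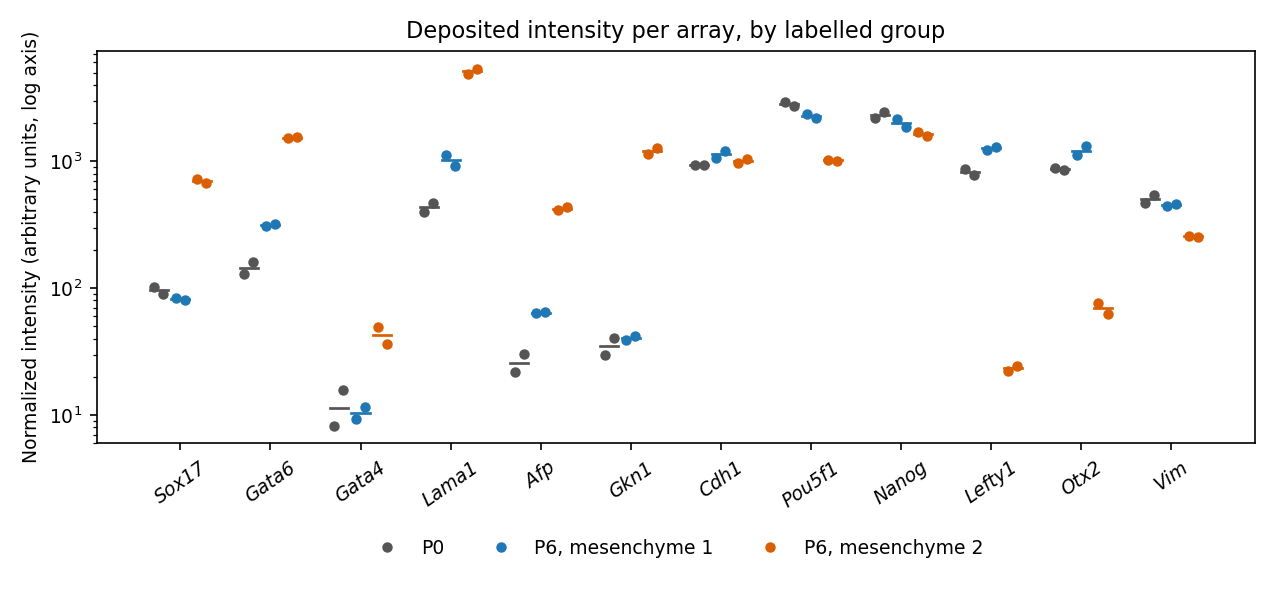
Normalized intensity (arbitrary units, log axis) of 12 genes on each of the 6 arrays. Points are single arrays, horizontal lines are geometric means of the 2 arrays of a group, and colours are the labelled groups; Sox17 lies at 96.5, 81.8 and 701 in P0, mesenchyme 1 and mesenchyme 2, and Lefty1 at 823, 1263 and 23.3.

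The first comparison asks how endoderm kept for 6 passages on mesenchyme 1 differed from unpassaged endoderm. The largest rise on the arrays labelled mesenchyme 1 was that of Ddx5, an RNA helicase, at 3.88 ± 0.116 (from 15.6 to 229, 14.7-fold). It was followed by Fgf4, a growth factor of the early embryo, at 3.28 ± 0.213 (from 13.5 to 131), and by the integrin subunit Itgav at 2.53 ± 0.129. Mcm7, a subunit of the replication helicase, rose by 2.04 ± 0.15, the transcription factor Wt1 by 2.03 ± 0.101 and the secreted factor Ptn by 2.02 ± 0.125. Atad2, Zfp457, Ctps2, Larp4b, Hapln4 and Ppp1cc rose by 1.81 to 2.29. The largest falls were those of Usp18, the protease that removes the ubiquitin-like protein ISG15, by 2.99 ± 0.101 (from 358 to 45.1), of the hormone gene Sct by 2.61 ± 0.127 and of Nbl1, a secreted BMP antagonist, by 2.57 ± 0.184. The transcription factors Gata2, Dlx3 and Gata3 fell by 2.54 ± 0.203, 2.34 ± 0.216 and 2.30 ± 0.301. Bcl3, Isg15, Rhox6, Hspb8, Ly6h and Gprc5a fell by 2.04 to 2.47. The order below Ddx5, Usp18 and Sct rests on low levels: Fgf4 stood at 4.97-fold with 16 added and 2.85-fold with 50 added, Itgav at 3.47-fold and 2.22-fold, and Nbl1 at 2.98-fold and 1.87-fold, where its call was lost.

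Among the gene lists, the interferon-stimulated list was lower on mesenchyme 1 than in P0: 4 of 14 measured members fell, among them Usp18 and Isg15 (by 2.39 ± 0.121), and none rose (list median -0.53, adjusted p = 0.00779). The immediate early and stress list was lower (median -0.74, adjusted p = 0.0146), with 3 of 14 members down, including Junb by 1.53 ± 0.0935 and Fosb by 1.32 ± 0.109. The BMP target list was lower (median -0.60, adjusted p = 0.00885), with Gata2 and Id2 the 2 of 8 members that fell. Apolipoproteins and lipid transport were lower (median -0.84, adjusted p = 0.0183), although only Fabp3, a fatty acid binding protein, fell by the required 2-fold among 7. Oxidative phosphorylation was lower by a small step (median -0.28, adjusted p = 0.00779), with none of 25 members changed 2-fold; its brightest members Atp5b and Cox5a differed by 0.03 ± 0.0871 and -0.52 ± 0.102. The S phase list was higher (median 0.30, adjusted p = 0.0183), with Mcm7 and the cyclin Ccne2 the 2 of 17 members that rose. These p-values come from camera with a preset correlation. With an estimated correlation none of the 6 calls held (adjusted p = 0.39 for each). The directional fry test called all 6 (adjusted p = 0.000387 to 0.00394), but it called 23 of the 30 lists.

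The lists of the endoderm itself did not pass the preset camera test between mesenchyme 1 and P0. Of 17 definitive endoderm genes, Gata6, an endoderm transcription factor, rose by 1.13 ± 0.118 and 5 fell, including the keratins Krt18 by 1.65 ± 0.0947 and Krt8 by 1.46 ± 0.0849 (list adjusted p = 0.0613). Of 19 parietal endoderm genes, 4 rose, with Srgn at 1.27 ± 0.0953 and the laminin subunit Lama1 at 1.23 ± 0.131, and 2 fell, Nid1 and Sparc (adjusted p = 0.453). Of 16 visceral endoderm genes, Amn rose by 1.76 ± 0.0975 and Afp, the alpha-fetoprotein gene, by 1.32 ± 0.157, while Rbp4, the retinol carrier, fell by 1.79 ± 0.11 and Car4 by 1.02 ± 0.0889 (adjusted p = 0.182). Of 20 pluripotency genes, Fgf4 rose and Klf4 fell, by 1.34 ± 0.0969 (adjusted p = 0.398); Pou5f1 and Nanog differed by -0.31 ± 0.0925 and -0.21 ± 0.111. The keratin and junction list had 6 of 18 members down, led by Krt7 at 1.98 ± 0.144, and none up (adjusted p = 0.112). Of 12 mesenchyme and fibroblast genes, a list kept for cells carried over from the co-culture, Pdgfra and Col5a1 rose, by 1.06 ± 0.0987 and 1.02 ± 0.0872, and none fell (median 0.41, adjusted p = 0.186). Leaving out single arrays took some of these below 2-fold. Without P0 replicate 1, Gata6, Car4 and Fabp3 stood at 0.97, -0.97 and -0.97, and Nid1 just short of 2-fold as well. Without P0 replicate 2, Id2 and Col5a1 stood at -0.99 and 0.98. Without mesenchyme 1 replicate 1, Nid1, Pdgfra, Col5a1 and Ccne2 stood at -0.96, 0.97, 0.98 and 0.93, and without its replicate 2, Id2, Sparc and Fabp3 stood at -0.83, -0.97 and -0.97.

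In all, 460 of 8396 genes and unnamed probes passed between mesenchyme 1 and P0, 220 higher and 240 lower, at a limma adjusted p under 0.05 and at least 2-fold; 26 of them differed at least 4-fold. The count was 209 with 16 added to every intensity, 94 with 50 added, 56 when the test itself was made against a 2-fold change, 283 for probes with a mean intensity of at least 50, and 4044 without the 2-fold limit. The fold of low genes moved with it: that of Ddx5 was 7.77 with 16 added and 4.26 with 50 added, and of the 56 named calls 14 were lost with 16 added, that of Afp among them at 0.94, 31 with 50 added, 28 when tested against a 2-fold change, and 3 with the mean of all probes of a gene, where Id2, Sparc and Ezh2 stood at -0.81, -0.54 and 0.79. With every array centred on its median the balance turned, to 231 higher and 230 lower.

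**Figure D2:**
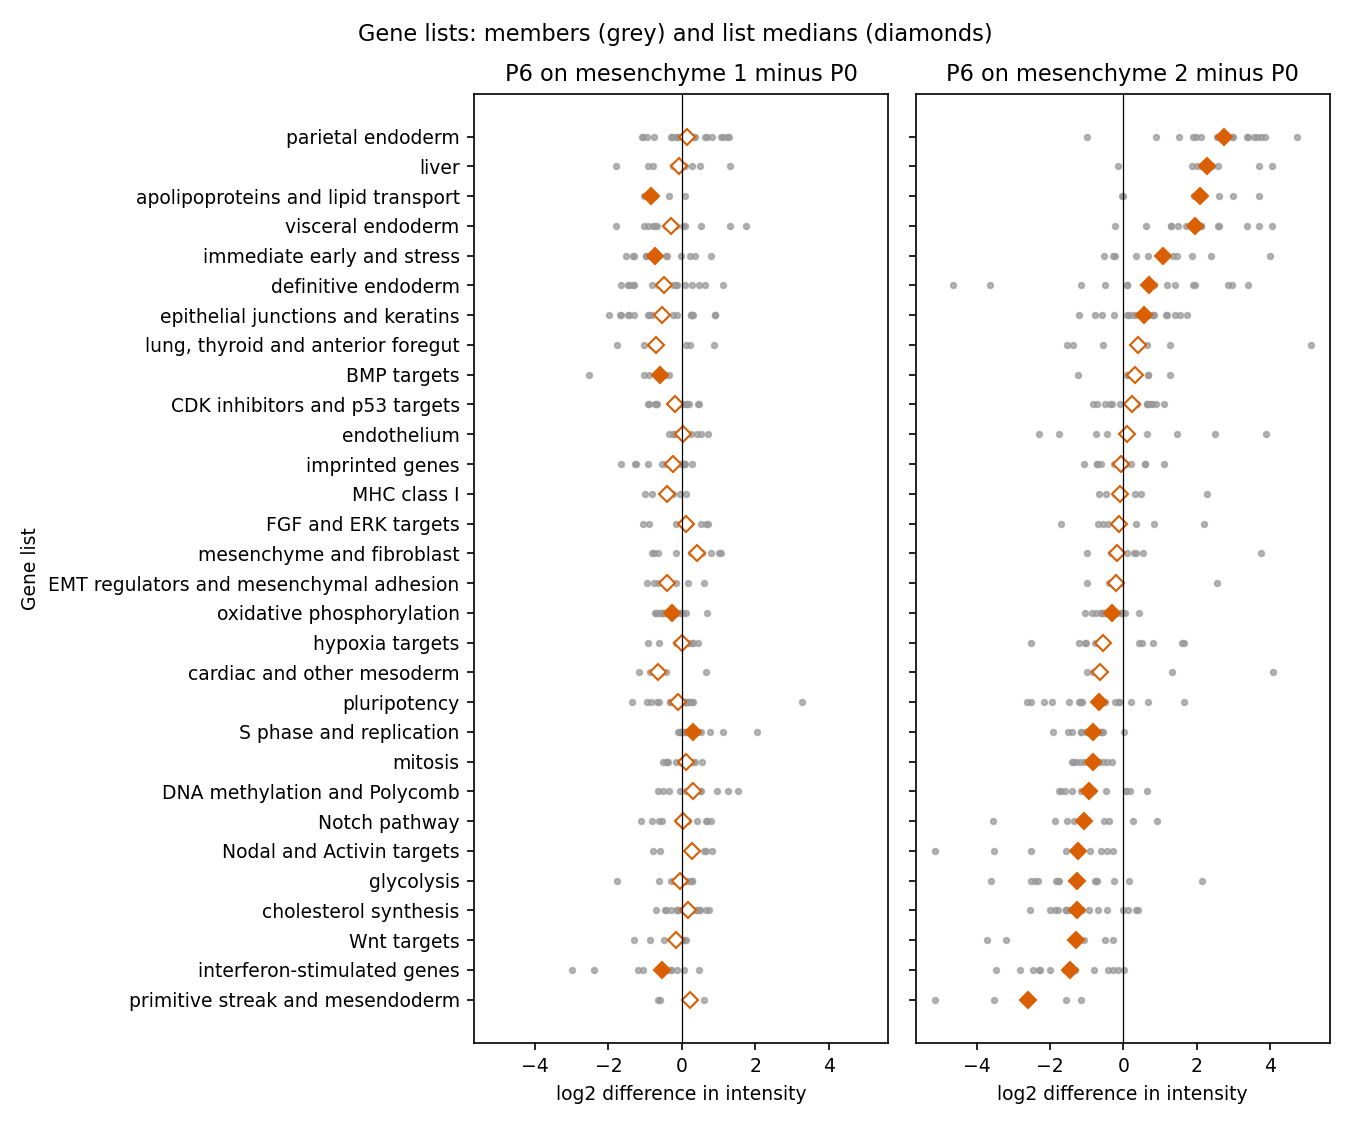
Differences from P0 (log2 of intensity) for the 30 tested gene lists on the arrays of mesenchyme 1 (left) and mesenchyme 2 (right). Grey points are list members, diamonds are list medians, and filled diamonds mark an adjusted p under 0.05 by camera with a preset correlation; the parietal endoderm median is 0.14 on the left and 2.75 on the right, and no filled diamond keeps its call with an estimated correlation.

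The second comparison sets 6 passages on mesenchyme 2 against unpassaged endoderm. On the deposited scale the largest rise was that of Aqp8, a water channel, at 6.15 ± 0.112 (from 9.66 to 687, 71.1-fold), and the next that of the keratin Krt23 at 5.75 ± 0.194 (from 15.8 to 853). Gkn2 and Gkn1, secreted proteins of the stomach lining, rose by 5.13 ± 0.0974 (from 66.8 to 2339) and 5.11 ± 0.154 (from 34.7 to 1203). The order rests on P0 levels near the low end of the table: with 16 added Aqp8 stood at 27.4-fold and Gkn2 at 28.4-fold, and with 50 added at 12.4-fold and 20.5-fold. Dram1, Srgn, Hkdc1, Mgst2, Klb, B4galnt2, Drp2 and Slc34a2 rose by 4.25 to 4.76. Aire, known as the autoimmune regulator, changed most among the falls on this scale, at -5.26 ± 0.135 (from 560 to 14.7). It was followed by Lefty1, an inhibitor of Nodal signalling, at -5.14 ± 0.101 (from 823 to 23.3), and by Trh, which encodes thyrotropin-releasing hormone, at -4.65 ± 0.0993 (from 1654 to 66.0). This order rests on low levels too: with 16 added Aire, Lefty1 and Trh stood at 18.8-fold, 21.3-fold and 20.4-fold, and with 50 added at 9.42-fold, 11.9-fold and 14.7-fold. Prmt8 and Khdc3 changed by -4.32 ± 0.112 and -4.19 ± 0.136. Upp1, Notum, Otx2, Aldoc, Notch4, Lefty2 and Isg15 fell by 3.47 to 3.84.

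Genes of the extraembryonic endoderm were higher on the arrays labelled mesenchyme 2, which also carried 7.26 times the Sox17 signal of P0. Of 19 parietal endoderm genes, which include basement membrane components, 17 rose and none fell (median 2.75, adjusted p = 4.13e-09). Srgn rose by 4.74 ± 0.0953 and Hs3st1 by 3.86 ± 0.0911. Of the others, Vim and Nid1 differed by -0.98 ± 0.102 and 0.89 ± 0.126. Of 16 visceral endoderm genes, 14 rose and none fell (median 1.96, adjusted p = 1.05e-06), among them Afp by 4.04 ± 0.157 (from 25.7 to 424) and the apolipoprotein gene Apoa1 by 3.69 ± 0.156. Of 8 liver genes, 7 rose (median 2.27, adjusted p = 0.000865); Afp, Apoa1 and others stand in the visceral list too. Of 7 genes of apolipoproteins and lipid transport, 5 rose, with Fabp3 at 2.98 ± 0.0955 (median 2.10, adjusted p = 0.00407). With an estimated correlation these lists stood at adjusted p = 0.0863, 0.0863, 0.14 and 0.116.

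Of 17 definitive endoderm genes, 7 rose, Sox17 among them, and 3 fell (median 0.71, adjusted p = 0.0372; adjusted p = 0.252 with an estimated correlation, and 0.0637 for probes with a mean intensity of at least 50). Gata6 rose by 3.40 ± 0.118 and the related factor Sox7 by 2.95 ± 0.12, and Gata4 by 1.90 ± 0.304 from 11.4 to 42.5. Gata6 and Sox7 stand on the parietal endoderm list too, so their rises are not particular to definitive endoderm. The falls were Trh, the anterior factor Otx2 by 3.64 ± 0.127, and Eomes, a factor of the primitive streak, by 1.15 ± 0.106. Of 18 genes of epithelial junctions and keratins, 5 rose, including the desmosome gene Dsg2 by 1.73 ± 0.116 and the tight junction gene Ocln by 1.53 ± 0.157, and Cldn3 fell by 1.21 ± 0.122 (median 0.57, adjusted p = 0.0313; adjusted p = 0.392 with an estimated correlation).

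Primitive streak, Nodal and pluripotency genes were lower on the arrays labelled mesenchyme 2 than on those labelled P0. All 6 measured primitive streak genes fell (median -2.61, adjusted p = 6.63e-05), with Lefty1 first and Lefty2 next, at -3.52 ± 0.0983. Of 8 Nodal and Activin targets, 4 fell, all of them on the streak list too (median -1.23, adjusted p = 0.000155). Of 20 pluripotency genes, 9 fell and Klf4 rose, by 1.66 ± 0.0969, a call lost with the mean of all its probes, at 0.43 (median -0.67, adjusted p = 0.000552). Utf1 and Tdgf1 fell by 2.63 ± 0.0905 and 2.52 ± 0.0922, and Pou5f1 by 1.48 ± 0.0925, from 2833 to 1018. Nanog, at 2310 in P0 and 1632 on mesenchyme 2, differed by -0.50 ± 0.111 and missed the 2-fold limit. Of 7 Wnt targets, 5 fell (median -1.30, adjusted p = 0.00069), led by Notum, which inactivates Wnt proteins, by 3.71 ± 0.0942 and by the cyclin Ccnd1 by 3.20 ± 0.139. Each of these lists stood at adjusted p = 0.0863 with an estimated correlation.

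Metabolic and cell cycle lists were lower as well. Of 17 glycolysis genes, 11 fell, with Aldoc at -3.62 ± 0.128 and Pdk1, a kinase that holds back pyruvate dehydrogenase, at -2.51 ± 0.0831; the enolase gene Eno2 rose by 2.15 ± 0.131 (median -1.27, adjusted p = 1.43e-05). Of 18 cholesterol synthesis genes, 11 fell and none rose, led by Dhcr7 by 2.54 ± 0.135 and Mvd by 1.99 ± 0.111 (median -1.27, adjusted p = 9.02e-05). Of 17 S phase genes, 6 fell, including Ccne1 by 1.92 ± 0.0939 (median -0.83, adjusted p = 8.71e-06), and of 15 mitosis genes 5 fell, including Top2a by 1.41 ± 0.108 (median -0.84, adjusted p = 1.47e-05). Of 14 interferon-stimulated genes, 9 fell, with Isg15 by 3.47 ± 0.121 and Oasl2 by 2.81 ± 0.143 (median -1.46, adjusted p = 1.89e-05). Oxidative phosphorylation had a median of -0.31 with 1 of 25 members, Cox7a2, down 2-fold (adjusted p = 0.00145). These 6 lists stood at adjusted p = 0.0863 with an estimated correlation. Of 10 Notch pathway genes 6 fell, with Notch4 by 3.56 ± 0.107 and Jag2 by 1.87 ± 0.096 (adjusted p = 0.00669), and of 13 DNA methylation and Polycomb genes 5 fell, with Jarid2 by 1.76 ± 0.213 (adjusted p = 0.00737); with an estimated correlation these stood at adjusted p = 0.119 and 0.14. The immediate early and stress list moved the other way: 9 of 14 members rose and none fell, with the stress factor gene Ddit3 16.1-fold higher (from 61.3 to 984) and Atf3 at 2.38 ± 0.1 (median 1.09, adjusted p = 0.00152; adjusted p = 0.156 with an estimated correlation). Of 12 mesenchyme and fibroblast genes only Pdgfra passed, at 3.75 ± 0.0987, and it is on the parietal endoderm list too (median -0.18, adjusted p = 0.818).

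Between mesenchyme 2 and P0, 1573 of 8396 genes and unnamed probes passed, 863 higher and 710 lower, and 271 of them differed at least 4-fold. With every array centred on its median the balance turned, to 758 higher and 812 lower. The count was 718 with 50 added to every intensity, 678 when the test was made against a 2-fold change and 5413 without the 2-fold limit. With 50 added, 22 of the 24 genes named for the largest changes moved by more than 1.5 times (median fold 21.6 to 7.83; 13 of them with 16 added), and 14 of the 79 named calls were lost (5 with 16 added; 15 when tested against a 2-fold change); without mesenchyme 2 replicate 2, Cox7a2 stood at -0.97 and lost its call.

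The third comparison sets the cultures on the 2 mesenchymes against each other, both after 6 passages. Krt23 was 42.6-fold higher on mesenchyme 2 (5.41 ± 0.194), Myl3, a myosin light chain, by 4.96 ± 0.119, Gkn1 by 4.89 ± 0.154 and B4galnt2 by 4.76 ± 0.125. Aqp8, Mgst2, Nxf7, Apoa1, Gkn2, Sphk1, Ddit3 and S100a1 were higher by 4.40 to 4.72. Lefty1 was lower by 5.76 ± 0.101, at 1263 on mesenchyme 1 and 23.3 on mesenchyme 2 (54.2-fold), and Aire by 5.52 ± 0.135. The growth factor gene Fgf15 was lower by 4.71 ± 0.222 and Prmt8 by 4.21 ± 0.112. Enox1, Trh, Pou3f1, Otx2, Notch4, Fgf4, Ptn and Notum were lower by 3.84 to 4.18.

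On mesenchyme 2 against mesenchyme 1, 18 of 19 parietal endoderm genes were higher (median 2.38, adjusted p = 5.64e-08), as were 14 of 16 visceral endoderm genes (median 2.23, adjusted p = 2.2e-06), and none of either list was lower. With an estimated correlation both stood at adjusted p = 0.118. Of 17 definitive endoderm genes 10 were higher and 2 lower (median 2.03, adjusted p = 0.00558; adjusted p = 0.161 with an estimated correlation). Of 14 immediate early and stress genes 11 were higher and Hsph1, a heat shock protein, lower (median 1.93, adjusted p = 0.000152; adjusted p = 0.134 with an estimated correlation). Of 17 S phase genes 10 were lower, with Mcm7 by 3.20 ± 0.15 (median -1.36, adjusted p = 3.35e-06; adjusted p = 0.118 with an estimated correlation). Of 20 pluripotency genes 8 were lower and 2 higher, Klf4 by 3.01 ± 0.0969 and Tbx3 2.46-fold (adjusted p = 0.0036; adjusted p = 0.124 with an estimated correlation). Pou5f1 was lower by 1.16 ± 0.0925, at 2280 and 1018. Of 13 DNA methylation and Polycomb genes 7 were lower, led by the DNA methyltransferase gene Dnmt3b by 2.92 ± 0.0846, and Ring1 higher (adjusted p = 0.00115; adjusted p = 0.124 with an estimated correlation). Of 8 BMP targets 4 were higher, led by Id2 at 2.31 ± 0.137 and Id1 at 1.55 ± 0.104 (adjusted p = 0.00558; adjusted p = 0.172 with an estimated correlation). The interferon-stimulated list had 6 members lower, led by Irf1 by 2.77 ± 0.0982, and Usp18 higher by 1.40 ± 0.101 (adjusted p = 0.038; adjusted p = 0.169 with an estimated correlation). It lost its call with the replicate number as a block, and without mesenchyme 2 replicate 1, at adjusted p = 0.0542 each. Lower too were cholesterol synthesis (12 of 18 members), glycolysis (10 of 17, with Eno2 higher by 2.35 ± 0.131) and the primitive streak list (5 of 6), and apolipoproteins and lipid transport were higher (5 of 7), each at adjusted p = 0.000341. Mitosis (4 of 15) and Nodal targets (5 of 8) were lower at adjusted p = 0.000103 and 0.00153. These 6 lists stood at adjusted p = 0.124 with an estimated correlation. Liver genes (7 of 8) and epithelial junctions and keratins (10 of 18, with the transcription factor gene Grhl2 lower by 1.18 ± 0.1) were higher at adjusted p = 0.000848 and 0.00281, and Notch pathway genes (5 of 10, with the target gene Hes1 higher by 1.75 ± 0.138) lower at adjusted p = 0.0125. With an estimated correlation these stood at adjusted p = 0.153, 0.215 and 0.153, and the Notch list also lost its call for probes with a mean intensity of at least 50 (0.0548).

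In all, 2132 genes and unnamed probes passed, 1167 higher and 965 lower, between the cultures on the 2 mesenchymes, with 445 at least 4-fold apart. With every array centred on its median this balance turned as well, to 1040 higher and 1113 lower. The count was 1042 with 50 added to every intensity, 1127 when tested against a 2-fold change and 5851 without the 2-fold limit. With 50 added, 23 of the 24 genes named for the largest changes moved by more than 1.5 times (median fold 22.9 to 9.5), Krt23 stood at 12.9-fold, below Gkn2 at 15.7-fold, and 14 of the 90 named calls were lost.

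Changes shared by both cultures were examined last. Both P6 cultures differed from P0 in passage and in growth on mesenchyme rather than gelatin, so shared changes cannot separate these. The P6 arrays of both mesenchymes, averaged with equal weight, differed from P0 in 453 genes and unnamed probes, 230 higher and 223 lower (212 and 241 with arrays centred on their medians), and 85 were called in the same direction in each culture against P0. Of these, 41 were higher, among them Aqp8, Srgn, Afp, Amn, Lama1, Itgav, Ddx5 and Gata6, and 44 lower, among them Isg15, Usp18, Khdc3, Gata2, Gata3, the Wnt target Sp5, the transcription factor Irx3 and the hexokinase gene Hk1. Lists drawn independently would share 22.6 and 20.3. Both comparisons use the same P0 arrays, and groups simulated as unchanged shared 0 in each of 100 simulations, a count that the 2-fold limit nearly fixes and that says little of the shared calls. Any deviation of the single P0 culture enters both comparisons, and it was not measured; the P0 arrays were not split, which would leave 1 array per side. Another 48 were lower on mesenchyme 1 and higher on mesenchyme 2, against 24.7 for independent lists, and 20 went the opposite way, against 18.6. Across genes, log2 differences of the 2 cultures from P0 correlated at 0.0469 (Pearson) and 0.0387 (Spearman). Unchanged groups sharing the P0 arrays gave a mean Pearson correlation of 0.501 in the simulations. The shared arrays alone set that value when differences are only noise, so it is no reference for the observed correlation. The differences had a covariance of 0.0213 against 0.0117 simulated for unchanged groups, 0.00953 apart. Gata6 lost its call on mesenchyme 1 without P0 replicate 1, at 0.97, and Gata2 its call on mesenchyme 2 without replicate 1 of that group, at -0.97.

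With the duplicates averaged, so that the 2 P6 cultures were set against the single P0 sample, limma called 0 genes for the mean of both cultures against P0, with 21 at an unadjusted p under 0.05 and a smallest adjusted p of 1. Entered as arrays, the same comparison called 453. However, the averaged fit has 1 residual degree of freedom and takes its spread from the difference between the cultures, so its lack of calls was largely set by the design. Spread between cultures grown alike was not measured, and the gene calls above concern these RNA samples. With duplicates as arrays, 243 were called with 16 added to every intensity and 133 with 50 added, and 85 shared calls became 25 and 6. Of the gene lists, 14 passed for the mean of both cultures, among them the parietal endoderm list (12 of 19 higher, median 1.53, adjusted p = 1.13e-08) and the interferon-stimulated list (7 of 14 lower, median -1.08, adjusted p = 1.53e-06). With an estimated correlation both stood at adjusted p = 0.0865, and none of the 14 held.

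**Figure D3:**
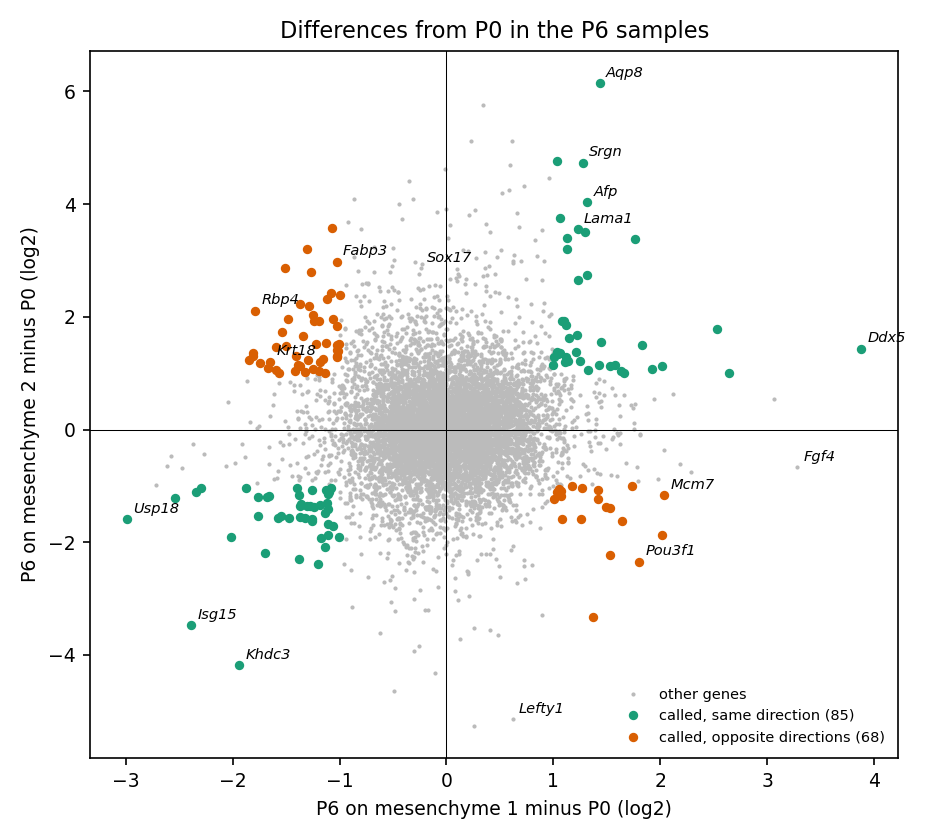
Difference from P0 (log2 of intensity) on mesenchyme 1 (horizontal axis) and on mesenchyme 2 (vertical axis) for each of 8396 genes and unnamed probes. Green points are the 85 called in the same direction in both, orange points the 68 called in opposite directions and grey points all others. The cloud has a Pearson correlation of 0.0469 across genes. Unchanged groups simulated with shared P0 arrays gave a mean of 0.501. The sharing alone sets that value when differences are only noise, so it is no reference for the cloud.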

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

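The checks of explanations in this part were chosen after the patterns were seen, though median scaling and the tests of the fixed lists were planned beforehand. The list of trophoblast genes was written after the patterns were seen too, without the genes already seen among the falls. The bounds for that list and for the 12 falls with 50 added were set before those tests were run. The other bounds were revised after their results. In the P6 cultures, 68 features were called in opposite directions against P0 on the 2 mesenchymes, which by arithmetic places each at least 4-fold apart between the cultures. Among the named ones, Rbp4 stood at -1.79 on mesenchyme 1 and 2.11 on mesenchyme 2, Krt18 at -1.65 and 1.20, Pou3f1 at 1.80 and -2.35, and Dnmt3b at 1.53 and -1.39. The list medians, mesenchyme 2 minus mesenchyme 1, differed between the cultures by -1.36 for S phase and replication, by 2.27 for apolipoproteins and lipid transport and by 1.93 for immediate early and stress genes, each list having been called in opposite directions against P0 in the preset test and in neither with an estimated correlation.

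The Sox17 transcript was higher on the arrays labelled mesenchyme 2 than on the others, although all groups were sorted on its reporter. Single arrays exchanged between groups are argued against: the lowest correlation within a group, 0.9934, lies above the highest between groups, 0.9596. A lower share of Sox17-expressing cells stays open: the 20 pluripotency differences (P0 minus mesenchyme 2) had a median of 0.67 and an SD of 1.06, but their standard errors cover technical duplicates only, so this spread decides nothing. An exchange of whole groups stays open too, since the mesenchyme and fibroblast list, which co-culture might raise, had a median of -0.18 on mesenchyme 2 and 0.41 on mesenchyme 1 against P0 and passed in neither. A change in the state of the cells, or a real difference between the mesenchymes, stays open as well and was not tested.

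The cholesterol synthesis, glycolysis and replication lists were lower against P0 on the arrays labelled mesenchyme 2 in the preset camera test. Called lower were 11 of 18, 11 of 17 and 6 of 17 members, and Eno2 was higher. With an estimated correlation each list stood at adjusted p = 0.0863. After every array was centred on its median, the cholesterol list kept a median of -1.34 against P0. Array medians lay within 6.23% of each other, so centring could barely move a list and this outcome was set in advance. The close medians themselves argue against a factor common to a whole array left in the deposited values. They come from values the authors had normalized, so they say nothing of a difference that this step removed or made. For the cholesterol list, low intensities are argued against as the whole cause, as its median was -0.92 with 50 added. The glycolysis and replication lists were given no such bound. The 6 days of growth factors were the same in all groups, but no label gives a medium, serum or collection day per group, so these cannot be separated from the mesenchyme, which stays open and untested.

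Gata2, Gata3, Plac1 and Krt7, all known in trophoblast, were among the larger falls on mesenchyme 1; Plac1 was chosen after its values were seen (-2.01, from 70.5 to 17.5). With 50 added, 7 of the 12 named falls kept their call, Gata2 and Gata3 among them; outside the 12, Krt7 kept its call (-1.26) and Plac1 lost it (-0.84). That met the bound of at least 6 set beforehand. The margin was under 1.73, a calculated spread that treats the 12 genes as independent, which genes picked as the largest falls are not. Nbl1, Bcl3, Dlx3, Ly6h and Gprc5a lost their calls, so low intensities remain a possible explanation for part of the falls. Of 41 listed trophoblast genes 16 were measured, of which 6 fell and none rose (median -0.51, camera p = 0.0106 with the preset correlation and 0.0713 with an estimated one), while on mesenchyme 2 the median was -0.08, with 3 higher and 3 lower. Plac1, Gata2 and Gata3 were also called lower on mesenchyme 2, at -1.91, -1.22 and -1.04, while Krt7 missed the limit at -0.59. The falls of Plac1, Gata2 and Gata3 are thus not confined to mesenchyme 1. A deviation of the single P0 culture would enter both comparisons. A lower level of trophoblast transcripts on mesenchyme 1 remains a hypothesis that rests on the preset correlation.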

How the results depend on the processing

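Counts are given in the order mesenchyme 1 against P0, mesenchyme 2 against P0, mesenchyme 2 against 1, mean of both cultures against P0, and calls shared by both cultures, whose main values were 460, 1573, 2132, 453 and 85. With the adjusted p alone they were 4044, 5413, 5851, 4245 and 1458, and tested against a 2-fold change 56, 678, 1127, 96 and 8. With 50 added to every intensity, chosen after seeing the data, they were 94, 718, 1042, 133 and 6. With 16 added, also chosen after, the first, the mean and the shared count were 209, 243 and 25, and for a mean intensity of at least 50, chosen after, the first and the shared count were 283 and 46. An added constant shrinks the folds of dim probes by construction, and the intensity limit tests fewer features (6605). With duplicates averaged, limma called 0 genes for the mean (21 at an unadjusted p under 0.05), with 1 residual degree of freedom. Gene lists called were 0, 0, 0 and 0 with an estimated correlation, against 6, 19, 19 and 14; fry called 23 by its directional p for mesenchyme 1, and 30, 30, 30 and 30 by its mixed p, which asks whether genes change in either direction. Other settings stayed within 1.5 times. Leaving out each array gave 458 to 500, 1573 to 1609, 2128 to 2162, 465 to 494 and 83 to 107 genes, and 6 to 7, 19 to 19, 18 to 19 and 14 to 15 lists, the lone array being assumed to vary like the others. With the replicate number as a block the counts were 460, 1572, 2131, 452 and 85 and the lists 6, 19, 18 and 14; the list lost was the interferon-stimulated one between the mesenchymes. Numbers share only a name: deviations of same-numbered arrays correlated at -0.00307, -0.0073 and 0.0107. For 225 called values of named genes, 3629 of 3793 alternative values kept direction and call, 164 lost the call and 0 reversed. For 58 list calls 977 of 984 kept both under preset camera, 7 lost the call and 0 reversed. Part of both totals was fixed in advance. The adjusted p alone cannot lose a gene call. That setting, the test against a 2-fold change and the trend and robust priors leave camera unchanged, with 58 list values each. Leaving out an array of a group not compared mainly moves the shared spread. The background and detection settings planned for the scanner table were not run. Duplicate spread was 0.206 (log2 SD) in the lowest quartile of intensity (median 28.1) and 0.0768 in the highest (704), which limits small changes of dim genes.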

Other observations

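No test in this part was chosen after its result was seen, and only Actb, named last, was picked for its values. The lists not described above are given here with mesenchyme 1 against P0 first and mesenchyme 2 against P0 second. Of 8 endothelial genes none passed on mesenchyme 1. On mesenchyme 2, 3 rose and 2 fell: the adhesion gene Esam rose by 3.90 ± 0.0953 and the VEGF receptor gene Flt1 by 2.50 ± 0.106, while Robo4 fell by 2.31 ± 0.136 and Vwf by 1.75 ± 0.124 (list adjusted p = 0.737 and 0.818). Of 7 genes of lung, thyroid and anterior foregut, 2 fell on mesenchyme 1, Irx3 by 1.76 ± 0.133 and Id2 by 1.03 ± 0.137. On mesenchyme 2 Irx3 and Foxp1 fell by 1.53 ± 0.133 and 1.38 ± 0.182, while Gkn1 rose by 5.11 ± 0.154 and Id2 by 1.28 ± 0.137 (adjusted p = 0.261 and 0.787). Of 5 cardiac and other mesoderm genes, Myl4 fell on mesenchyme 1 by 1.17 ± 0.11, and Myl3 and Myl7 rose on mesenchyme 2 by 4.09 ± 0.119 and 1.33 ± 0.193 (adjusted p = 0.117 and 0.818). Of 8 MHC class I genes, B2m, the light chain, rose on mesenchyme 2 by 2.29 ± 0.0847, from 685 to 3344, and no other passed in either (adjusted p = 0.112 and 0.818). Among hypoxia targets none of 11 passed on mesenchyme 1; on mesenchyme 2 Vegfa rose by 1.65 ± 0.103 and P4ha1 by 1.60 ± 0.0938, and 4 fell, led by Pdk1 by 2.51 ± 0.0831 and Egln1 by 1.22 ± 0.116 (adjusted p = 0.902 and 0.659).

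Of 14 imprinted genes 3 fell on mesenchyme 1, Phlda2 by 1.66 ± 0.0882, Peg10 by 1.28 ± 0.134 and Slc22a18 by 1.26 ± 0.146; on mesenchyme 2 Impact rose by 1.11 ± 0.0867 and Snrpn fell by 1.06 ± 0.0877 (adjusted p = 0.112 and 0.576). Of 9 FGF and ERK targets, Phlda1 fell on mesenchyme 1 by 1.07 ± 0.0858, and on mesenchyme 2 Dusp4 rose by 2.20 ± 0.105 and Etv5 fell by 1.71 ± 0.104 (adjusted p = 0.636 and 0.756). Of 6 genes of EMT and mesenchymal adhesion none passed on mesenchyme 1, and the repressor gene Snai1 rose on mesenchyme 2 by 2.56 ± 0.121 (adjusted p = 0.445 and 0.578). Of 17 CDK inhibitors and p53 targets none passed on mesenchyme 1 and Cdkn1a, an inhibitor of cell cycle kinases, rose on mesenchyme 2 by 1.10 ± 0.0904 (adjusted p = 0.261 and 0.331); that gene stood at 0.99 with the mean of all its probes. On mesenchyme 2 against mesenchyme 1 this list was higher (adjusted p = 0.0273; adjusted p = 0.161 with an estimated correlation, and 0.0515 without mesenchyme 1 replicate 1).

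Too few members were measured to test the other 6 lists. The pancreatic factor gene Rfx6 fell on mesenchyme 1 by 1.37 ± 0.205 and rose on mesenchyme 2 by 2.22 ± 0.205, from 35.1 to 164. The mucin gene Muc13, of 2 intestinal genes, rose on mesenchyme 2 by 2.74 ± 0.131, and the neural gene Stmn2 fell there by 2.79 ± 0.0935, from 590 to 85.4. Laptm5, Smo and Hoxa13, the single measured members of the blood, Hedgehog and Hox lists, passed in neither. Actb, chosen after its values were seen, encodes a cytoplasmic actin often used as a reference and fell by 1.58 ± 0.0823 on mesenchyme 1 and by 1.56 ± 0.0823 on mesenchyme 2 at its brightest probe, from 4217 to 1410 and 1428. The gene has 5 probes, and the fold changes of the others are not given here.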
